A study of Rattus norvegicus with 12 samples.

How the data were processed

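Total RNA (3 microgram) of 12 rat soleus muscles was reverse transcribed at 50 degrees Celsius with gene-specific primers and a radioactive nucleotide, per the labels' protocols. The deposited values were 1 intensity per probe and array, on a linear scale, for 1185 probes without missing values. Image analysis, background treatment and scaling by the authors are not given in the sources used here. The values themselves show no scaling between arrays, since array medians ran from 4181 to 7965, and no background subtraction, since the lowest intensity of each array was 3239 or more. The probes carry IDs only, which matched 0 entries of the rat gene table given for this work, so 0 of the 24 gene lists written before the data were examined could be tested, and the planned check of the transferred FAK gene could not be made.

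Groups were taken from the sample titles, which give 6 FAK and 6 FAK+FRNK muscles. The titles hold a number for all muscles but 1 of the FAK+FRNK group, which is called unnumbered here. Numbers 440 and 441 occur in both groups and, given a design that compares both legs of an animal, were read as pairs. Whether 422 is 442 misread, and whether 437-2 and 438-2 are repeats of 437 and 438, is not stated. The series therefore could not be analysed as 6 pairs, and the main fit had no pairing term. Where samples may share an animal the p-values measure only the spread between these samples. The pairing was checked by the correlation of deviations from the group means. It gave 0.32 and 0.18 for the numbered pairs, both of which lie in the same intensity set. They ranked 3 and 8 of the 36 combinations across the groups, so the check does not settle the pairing.

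Background was corrected on each array with the normexp method (offset 50), arrays were scaled by quantile normalization, and log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted over 1185 probes, threshold 0.05). Normexp estimates background from the intensities themselves, so a log2 difference of a dim probe depends on that estimate, and log2 differences without it are compressed. The choice of quantile scaling followed a rule set before the data were examined, as did the test, the alternatives and the rule for named probes. Background correction was not part of that rule and is the usual step for arrays without a corrected column. The rule foresaw 10 probes per direction. Since no probe has a gene name, 2 per direction are named here, those with the smallest p, and probes R507, R565, RG270, RG388 and RG011 were chosen after their values were seen. The 4 brightness classes of 296 or 297 probes were set by the mean log2 signal over all 12 arrays.

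Single values per array were compared with exact permutation tests over all 462 splits of 6 against 6, and also with permutation within the 2 intensity sets, which were found in the data by the widest gap between array medians. Hybridisation dates and filters are not given in the sources used here. The number of arrays limits the precision: the median 95% interval of a log2 difference was ± 0.44. The limma step was tested on simulated data in which 200 of 1185 probes were changed. It recovered 80.1% of 2-fold and 98.2% of 4-fold changes with 4.68% false calls among all calls, assuming independent normal errors with each probe's own spread.

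Alternatives were other scalings between arrays, an offset before log2, a filter on dim probes, the title number as a block, averaging of 437 with 437-2 and of 438 with 438-2, array weights, a robust variance trend, exact permutation per probe, and leaving out each muscle. Added after the data were seen were no background correction, subtraction of each array's minimum, the intensity set as a block, each set alone, splits within the sets, the place in the listing as a random block, and correlations between arrays after set means were taken out, alone, with group means, or with group means within each set. Excluding values at or below 0 did not apply, since there were none.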

Results

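Soleus muscles of female Wistar rats aged 3 months were transfected by electro-transfer and profiled 7 days later on radioactively labelled expression arrays. The soleus is a postural calf muscle made up mostly of slow, oxidative fibres. In 6 muscles an expression plasmid for focal adhesion kinase (FAK), a tyrosine kinase at the sites where cells attach to the extracellular matrix, was introduced together with an empty plasmid. In the other 6 muscles the FAK plasmid was introduced together with one for FRNK, the separately expressed C-terminal part of FAK, which lacks the kinase domain and acts as an inhibitor of FAK. All 12 muscles came from cage-control animals. The study compared FAK+FRNK with FAK alone between the 2 legs of an animal, so the question was which transcripts in FAK-transfected muscle depend on leaving FAK uninhibited. Each array carried 1185 probes, known here only by an ID, 702 in the R series and 483 in the RG series. No probe could be given a gene name, so neither the transferred FAK gene nor any muscle gene group could be followed by name.

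The 12 arrays fell into 2 sets by brightness. Median intensity lay between 4181 and 4502 in 6 arrays and between 7023 and 7965 in the other 6, and summed intensity ran from 7106128 to 9139398 and from 14951971 to 18061822. Each set held 3 FAK and 3 FAK+FRNK muscles. The background fitted to each array made up 77.4% to 86.8% of the median probe's intensity in the low-intensity set and 71.4% to 83.4% in the high-intensity set, so most probes were read as a small excess over background. Pooled over the sets, array medians differed between the groups by less than the spread within them, at 6073 ± 1772 (SD, n = 6) for FAK and 5832 ± 1729 (SD, n = 6) for FAK+FRNK (exact permutation test, two-sided p = 0.58). Within the low-intensity set the medians were 4462 ± 45.7 for FAK and 4266 ± 76.2 for FAK+FRNK (SD, n = 3), and within the high-intensity set 7683 ± 247 and 7399 ± 326 (SD, n = 3). A permutation within the sets gave p = 0.035 for this measure, which became 0.175 after Benjamini-Hochberg adjustment over the 5 array measures tested. The 10 brightest probes took 43.7% ± 2.05 of the background-corrected signal in FAK muscle and 45.8% ± 3.34 in FAK+FRNK muscle (SD, n = 6; exact permutation p = 0.21, Benjamini-Hochberg adjusted 0.66).

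**Figure D1:**
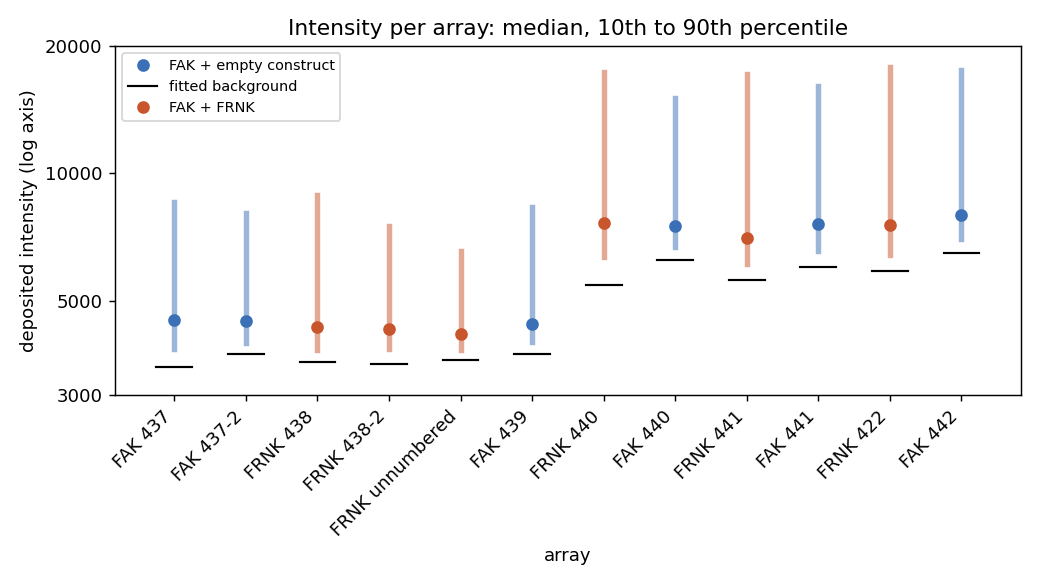
Deposited intensity of the 1185 probes on each array (log axis): points are medians, thick lines run from the 10th to the 90th percentile, and short black lines mark the fitted background, with FAK arrays in blue and FAK+FRNK arrays in orange. The 6 arrays on the left have medians of 4181 to 4502 and the 6 on the right of 7023 to 7965, with 3 arrays of each group in both.

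No probe passed the test for a difference between FAK+FRNK and FAK muscle. Of 1185 probes, 0 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.51. In the exact permutation test per probe, 52 probes that separated the groups without overlap would have sufficed for an adjusted p of 0.05. A larger number at its next smallest p would have done so too. Without overlap there were 2 probes, against 2.56 by chance (smallest adjusted p of this test = 0.68). With so coarse a test, its count of 0 adds little. At an unadjusted p under 0.05, limma listed 95 probes, 50 higher and 45 lower with FRNK, where 59.3 would be listed by chance, and the exact permutation test listed 85, of which 71 were among the 95. Of 100 splits of the 12 arrays into 6 and 6, the real one included, 16 listed at least 95 in limma, so chance is not excluded for this count. The limma count fell below that expected by chance with no scaling between arrays, to 22 (13 higher and 9 lower), and with division by the array sum, to 52 (23 higher and 29 lower). With each array divided by its median it was 79 (46 higher and 33 lower). The median log2 fold change over all probes was 0.0071, and 90% of the probes lay between -0.56 and 0.52. For 954 probes (80.5%) the 95% confidence interval of the difference lay within a 2-fold change in either direction. In simulated data with the spread of these arrays, limma recovered 80.1% of 2-fold and 98.2% of 4-fold changes when 200 probes were changed. These shares average over dim and bright probes and assume independent errors. They do not give the recovery for fewer changed probes or for dim ones. Leaving out the FAK muscle 439 gave 1 call, probe R507, with a log2 fold change of 1.49 (limma, adjusted p = 0.022) against 1.08 with all 12 arrays (limma, adjusted p = 0.61). The unadjusted count fell to 57 without the FAK muscle 440 and to 59 without the FAK muscle 437-2. It rose to 134 without the FAK+FRNK muscle 440 and to 126 without the FAK muscle 441.

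Among the probes with the smallest p in each direction, none passed the test. They were picked for their difference on these arrays, so the separation of the groups below in part restates the choice. Probe R156 had a mean log2 signal of 8.81 ± 0.34 in FAK and 9.53 ± 0.26 in FAK+FRNK muscle (SD, n = 6), a log2 difference of 0.71 ± 0.18 (SE; limma, adjusted p = 0.51). Probe R406 read 8.33 ± 0.75 and 9.34 ± 0.28 (SD, n = 6), a difference of 1.01 ± 0.30 (SE; limma, adjusted p = 0.51). In both, the signal with FRNK was above the FAK mean in 6 of 6 muscles. Between the muscles numbered 440, however, R156 read 9.20 in FAK+FRNK and 9.30 in FAK. Probe RG211 read 8.84 ± 0.36 in FAK and 7.95 ± 0.49 in FAK+FRNK muscle (SD, n = 6), a difference of -0.89 ± 0.23 (SE; limma, adjusted p = 0.51). Probe RG124 read 9.44 ± 0.74 and 8.16 ± 0.73 (SD, n = 6), a difference of -1.28 ± 0.38 (SE; limma, adjusted p = 0.51), and both lay below the FAK mean in 6 of 6 muscles with FRNK. Within the low-intensity and the high-intensity set the log2 differences were 0.95 and 0.48 for R156, 1.13 and 0.89 for R406, -1.10 and -0.68 for RG211, and -1.73 and -0.82 for RG124. In the model of 440 and 441 as pairs the differences were 0.37 for R156, 0.65 for R406, -0.84 for RG211 and -0.62 for RG124. These probes were dim, between the 2.95th and the 19.2nd percentile of brightness. Without background correction their log2 differences shrank to 0.082, 0.093, -0.068 and -0.13, and with an offset added before log2 to 0.43, 0.52, -0.42 and -0.69. Mean deposited intensities, without scaling, were 5395 in FAK and 5356 in FAK+FRNK muscle for R156, and 5295 and 5298 for R406. They were lower with FRNK for RG211 (5367 and 4840) and RG124 (5660 and 4992).

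**Figure D2:**
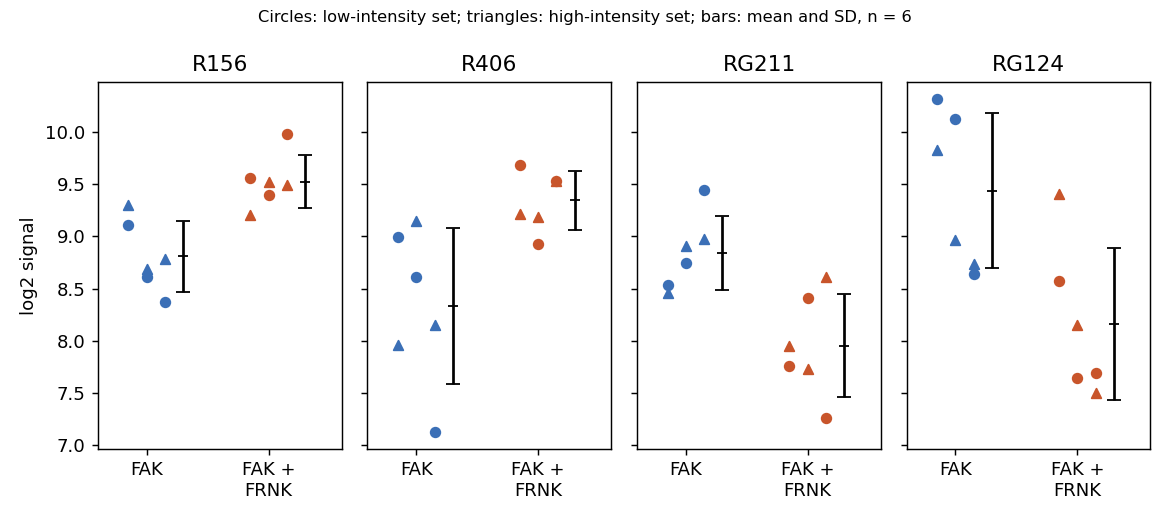
Log2 signal of the 2 probes with the smallest p in each direction, per muscle (circles, low-intensity set; triangles, high-intensity set), with the mean and SD of each group (n = 6) beside the points. R156 and R406 read higher and RG211 and RG124 lower with FRNK. In each probe 5 of the 6 FAK+FRNK muscles lie outside the range of the FAK muscles, yet none passed the adjusted test. The probes were picked for their small p, so this separation does not test them.

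The low p-values sat among the dim probes. Among the 297 dimmest probes 41 had an unadjusted p under 0.05 in limma, against 14.9 by chance. Among the 296 brightest 5 did, against 14.8. Limma here drew the variance of every probe toward 1 common value. The median SD within groups was 0.66 in the dimmest class and 0.29 in the brightest. That can make p too small for dim and too large for bright probes, so part of the contrast may come from the test. The counts were not split by brightness in the fit with a variance trend, in the exact test or over other splits of the arrays. The median absolute log2 difference was 0.31 in the dimmest and 0.099 in the brightest of these classes, with median standard errors of 0.34 and 0.17. The 95% interval lay within a 2-fold change for 287 of the 296 brightest probes (97.0%), compared with 138 of the 297 dimmest (46.5%). Among the next 296 probes below the brightest, 17 were listed, 13 of them higher with FRNK and 4 lower.

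**Figure D3:**
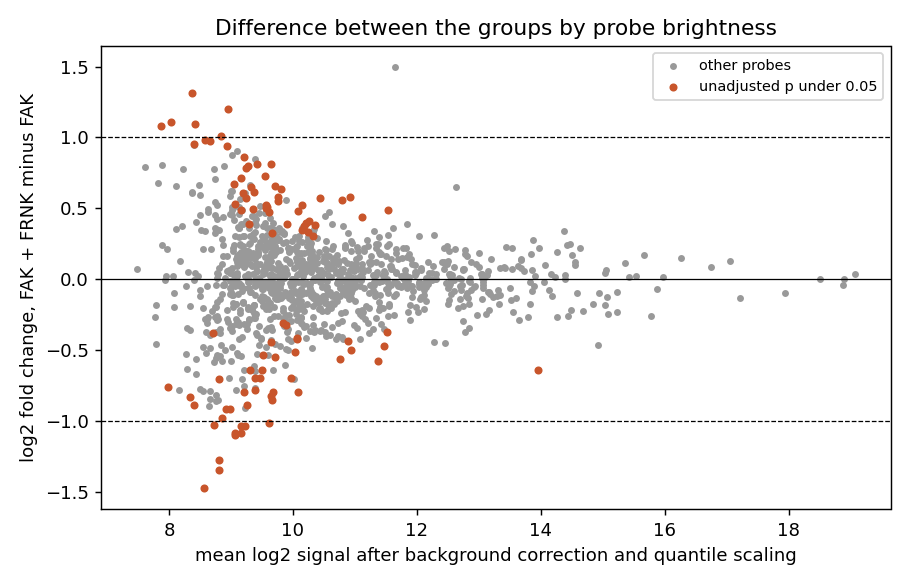
Log2 fold change of FAK+FRNK over FAK against mean log2 signal for 1185 probes, after background correction and quantile scaling; orange points have an unadjusted p under 0.05 and dashed lines mark a 2-fold change. The spread narrows from dim to bright probes, and 5 of the 296 brightest probes are orange.

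Over all probes at once, the distance between the group profiles did not pass the test. The root mean square log2 difference between the group means was 0.33, where the median over all 462 splits of the arrays into 6 and 6 was 0.27 (exact permutation test, p = 0.097). With splits made only within the intensity sets the p was 0.10 (exact permutation), and over the 296 brightest probes the difference was 0.19 (exact permutation, p = 0.59). The distance passed 0.05 without the FAK+FRNK muscle 440, at 0.37 (exact permutation, p = 0.043), and without the FAK muscle 441, at 0.38 (exact permutation, p = 0.035). It was 0.070 without background correction (exact permutation, p = 0.48) and 0.21 with an offset added before log2 (exact permutation, p = 0.13), and with no scaling between arrays it stayed at 0.33 with p = 0.68 (exact permutation). With each array divided by its median it was 0.33 with p = 0.16 (exact permutation). The differences measured in the low-intensity and in the high-intensity set correlated across probes with r = 0.16 over all 1185 probes (Spearman 0.14) (exact permutation over 400 relabellings within the sets, one-sided p = 0.215). Probes are not independent replicates. Limma listed 0 probes past an adjusted p of 0.05 within the low-intensity set and 1 within the high-intensity set, probe R565, with a log2 difference of 1.86 (limma, adjusted p = 0.033) against 0.61 over all arrays (limma, adjusted p = 0.76). With 3 muscles of each group per set, the value over all arrays is the mean of the 2 set differences. R565 therefore had the opposite sign in the low-intensity set, lower with FRNK. The high-intensity set holds the muscles 440, 441, 442 and 422, and with these as pairs R565 did not pass: its difference of 1.86 had a standard error of 0.16 in place of 0.20, on fewer residual degrees of freedom (limma, adjusted p = 0.13). At an unadjusted p under 0.05, 101 and 54 probes were listed in the sets, of which 3 were shared and 1 had the same sign, where 4.60 would be shared by chance.

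Numbers 440 and 441 stood in both groups and were read as both muscles of an animal. A muscle numbered 442 stood in the FAK group where 422 stood in the FAK+FRNK group. Deviations from the group means correlated across probes at 0.32 for the 440 muscles, 0.18 for the 441 muscles and 0.29 for 442 with 422. The median over all 36 FAK with FAK+FRNK combinations was 0.0037, and these 3 pairs ranked 3, 8 and 6 from the top. The highest combinations had unlike numbers and lay across the sets: FAK 437-2 and FAK 437 with FAK+FRNK 440, at 0.43 and 0.40. Without background correction the 3 pairs correlated at 0.48, 0.42 and 0.39. All 3 pairs lay in the high-intensity set, where the 6 other combinations ran from -0.47 to 0.29, the highest being 441 with 422. The set was also taken out in 3 ways, by set means, by set and group means, or by group means within each set. The correlation then exceeded the one that such centring gives for unrelated arrays of equal spread by 0.44 to 0.52 for the 440 muscles, 0.089 to 0.27 for the 441 muscles and 0.083 to 0.24 for 442 with 422, and 441 with 422 stood at 0.28 with group means taken out within each set. The muscles 437 and 437-2 correlated at 0.30, the highest of the 30 combinations within a group, and 438 and 438-2 at -0.25, where centring alone gives -0.20. With the set also taken out, in the same 3 ways, they differed from what the centring gives by 0.52 to 0.64 and by -0.065 to -0.0088. Each of these muscles was kept as its own sample. Treating 440 and 441 as pairs in a model of those 4 muscles gave 0 calls (limma, smallest adjusted p = 0.32), and adding 442 with 422 as another pair also gave 0 (limma, smallest adjusted p = 0.13), where the same 6 muscles without pairing gave 1, probe R565.

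After each set's mean was taken out, arrays listed at the same place in the 2 sets correlated across probes at 0.30 on average. The mean at other places, -0.060, follows from this value, since the deviations sum to 0 within a set. In the 720 ways to match the 6 low-intensity with the 6 high-intensity arrays, the listing order gave the highest mean (one-sided exact permutation p = 0.0014). The sets were found in these data and the matching by place was chosen after the data were seen, which this p does not allow for. The 296 brightest probes gave 0.19 (one-sided exact permutation p = 0.014) and the dimmest 25% gave 0.33 (one-sided exact permutation p = 0.0014). Of the 6 same-place pairs, 4 were of the same group, and with group means also taken out the mean correlation fell to 0.12, which 44 of the 720 matchings reached (one-sided exact permutation p = 0.061).

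**Figure D4:**
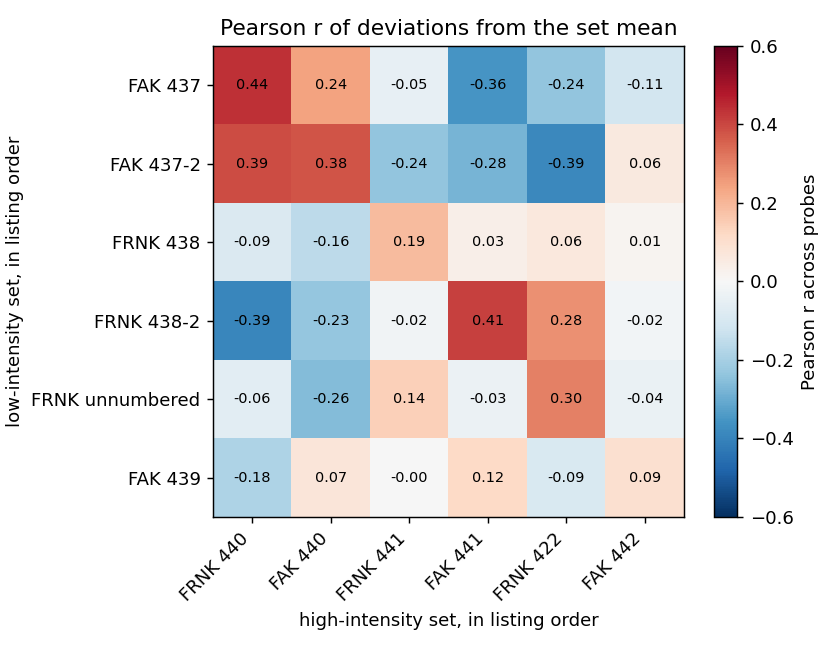
Pearson r across 1185 probes between arrays of the low-intensity set (rows) and the high-intensity set (columns), each as deviations from its set mean and in listing order; red is positive and blue negative. The diagonal, arrays at the same place in both sets, averages 0.30.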

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

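Probe RG388 had a log2 signal of 9.46 on the array of the FAK muscle 439, while the other 5 FAK arrays lay between 12.77 and 12.95. It was picked from 1185 probes for this value, so Dixon's criterion, which the gap met, restates the choice and does not test it. Over both groups of all probes, 212 of 2370 sets of 6 values met the criterion, and 3, RG388 included, had a gap at least as wide for their range. No explanation was tested.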

How the results depend on the processing

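The count of 0 probes past an adjusted p of 0.05 (limma) held under all alternatives but 2: without the FAK muscle 439 and in the high-intensity set alone it was 1, so leaving out 1 muscle gave 0 to 1. The smallest adjusted p over the alternatives ran from 0.022 to 0.999. The replicate block by title number gave 0 calls and 87 probes at an unadjusted p under 0.05, with a correlation of 0.34 within numbers; the block of 440 and 441 alone gave 0 and 90, that with 442 and 422 added 0 and 104. Those 6 muscles are the high-intensity set, so pairing ended its 1 call, R565 (adjusted p 0.033 without and 0.13 with pairs). The unadjusted count of 95 fell to 22 with no scaling between arrays, 52 with division by the array sum, 63 without the dimmest 25% of probes (889 probes tested) and 54 in the high-intensity set alone; leaving out 1 muscle gave 57 to 134. With no scaling the distance between the group means stayed at 0.33, so smaller differences do not account for the fall to 22. Division of each array by its median changes only the level of whole arrays, and it gave 79. Level differences between arrays, left in without scaling, therefore account for most of the fall to 22. For the other falls, apart from the smaller number of probes or muscles tested, the cause was not tested. Of the 22 and 52 probes, 18 and 48 were among the 95, and dividing by the sum put 23 higher and 29 lower. The distance between the group means ranged from 0.31 to 0.38 without 1 muscle and passed 0.05 without the FAK+FRNK muscle 440 (0.375) and without the FAK muscle 441 (0.377); the cause was not tested. It fell from 0.33 to 0.070 without background correction (exact permutation p = 0.48) and to 0.21 with the offset (p = 0.13). The exact permutation p was 0.68 with no scaling between arrays and 0.16 with each array divided by its median. The log2 differences of R156, R406, RG211 and RG124 kept their sign in the 29 alternatives in which they were measured. None passed the adjusted test there. These probes were picked for their small p and the alternatives use the same arrays, so a kept sign was likely beforehand and adds little. Leaving out 1 muscle gave 0.63 to 0.81, 0.78 to 1.17, -1.01 to -0.76 and -1.49 to -1.09. The correlation of the 441 muscles rose from 0.18 to 0.42 without background correction. Taking out the intensity set in 3 ways moved no correlation of the 440 or 441 muscles, 442 with 422, 437 with 437-2 or 438 with 438-2, measured from the value that centring alone gives, by more than the spread over all array pairs. That is a loose criterion for correlations of this size. By this measure 442 with 422 went from 0.29 to between 0.083 and 0.24. The 441 muscles went from 0.18 to between 0.089 and 0.27, and the 440 muscles from 0.32 to between 0.44 and 0.52. Signal over background limits what could be seen: for 46.5% of the 297 dimmest and 97.0% of the 296 brightest probes the interval lay within 2-fold.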

Other observations

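All tests of explanations below were chosen after the results were seen, except the count over splits of the arrays at an unadjusted p. Of 100 splits of the 12 arrays into 6 and 6, the real one included, 16 listed at least as many probes at an unadjusted p under 0.05 in limma as the 95 of the real split, and the highest other split listed 249, so chance is not excluded for the 95. For calls past an adjusted p of 0.05 the splits test nothing, since all 100 reach a real count of 0 whatever they hold; the highest other gave 16. The 249 and the 16 came from 1 split. Besides the real split, the 10 splits with the muscles 437, 437-2 and both of 440 on one side listed 111 to 249 probes (median 164) and the remaining 89 listed 9 to 163 (median 48), so a resemblance of these 4 arrays may account for the high counts; this grouping was chosen after the counts were seen, and no expected highest count was simulated.

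Probe RG270 had the widest group difference of the 592 brighter probes, with a log2 signal of 10.9 ± 0.56 in FAK and 12.4 ± 2.08 in FAK+FRNK muscle (SD, n = 6), a difference of 1.497 ± 0.76 (SE; limma, adjusted p = 0.64). It read 15.60 in the FAK+FRNK muscle 438-2, 13.68 in 422 and 13.06 in 440, above the 6 FAK muscles, and 10.34 to 11.22 in the other 3. The 3 arrays at the same places in the other set exceeded the remaining 6 by 0.50, with an SD of 0.40 among those 6, which bears on a defect of one physical filter only if filters were used again in listing order, so such a defect stays open. An effect of the FRNK construct that varies with uptake of plasmid may account for it, but the probe was picked for its difference, and the groups gave p = 0.14 (exact permutation), so this cannot be told apart from chance. A mark on single spots is also open and was not tested.

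The 2 intensity sets did not follow the constructs, since each held 3 muscles of each group. With this balance the pooled array medians could hardly differ between the groups (exact permutation p = 0.58). Within both sets the FAK medians were the higher on average (permutation within the sets, p = 0.035, Benjamini-Hochberg adjusted 0.175). One common factor on the whole intensity, background included, is argued against as the whole cause. The high-intensity set exceeded the low 2.36-fold in the brightest 10% of probes and 1.65-fold in the dimmest 10%. The log2 difference was 0.51 ± 0.11 (SE, n = 6 arrays per set). Background made up most of the median intensity, so these ratios do not exclude a common factor, such as exposure time, over an offset that did not scale with it. A difference in background together with one in labelling stays open too.

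Arrays listed at the same place in both sets resembled each other. This could come from 6 filters that were each hybridised 2 times in listing order, since no other matching of the 2 sets gave a mean correlation as high as 0.30 (one-sided exact permutation p = 0.0014). No number occurs in both sets, so 0 of the 5 same-place pairs with 2 numbers carry the same number, as in any other matching. This argues against shared animals only if the numbers name animals, which the titles do not state. Noise of dim spots as the whole cause is argued against, as the 296 brightest probes gave 0.19 (one-sided exact permutation p = 0.014). The dimmest 25% of probes gave a higher mean, 0.33 (one-sided exact permutation p = 0.0014). Among the brightest probes 1 of the 6 pairs, 437 with 440, was at -0.13, and these probes were not tested with group means taken out. With group means also taken out the mean correlation fell from 0.30 to 0.12 and did not pass the test (one-sided exact permutation p = 0.061), and filter lots or a fixed order of handling stay open. The constructs stay open too: the 2 pairs of unlike groups correlated at 0.41 and 0.44, but at 0.33 and 0.027 without background correction, 0.27 and 0.19 with group means taken out, and 0.36 and -0.13 in the brightest probes. With the set as a block and the place as a random block, limma gave 0 calls and 72 probes at an unadjusted p under 0.05.

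Probe RG011 read alike in both muscles numbered 440 and in both numbered 441, a likeness that was not tested. Its log2 signal was 14.87 and 15.20 in the FAK+FRNK and FAK muscles 440, 13.51 and 13.80 in those of 441, and 11.60 and 12.20 in 422 and 442, and between 13.64 and 14.39 in the 6 arrays of the low-intensity set.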
